A study of Mus musculus with 24 samples.

How the data were processed

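RNA sequencing of mouse tumour tissue gave 24 libraries, 3 for each combination of tumour line (MC38 or B16), genotype (parental Chek2-WT or Chek2 knock-out) and treatment (PBS or anti-PD-1), per the labels. Total RNA was extracted with Trizol and libraries were made with standard Illumina protocols, per the labels' protocols, which state neither strand, read length nor whether poly(A) RNA was selected. The submitters' processing notes list FastQC, STAR 2.5, Cuffnorm and DESeq and the genome build mm10, with no role or order. The deposited files hold 1 column of values per library for the same 55335 Ensembl mouse genes. The deposited values were taken as FPKM, since they are not whole numbers, their sums per library (310868 to 398474) are unequal and far below the fixed totals of CPM or TPM, and in genes with 1 transcript the value times the length piles up at 1 amount per library. The authors' normalization across libraries, annotation release and filters are not stated in the files.

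The deposited columns hold FPKM and not counts, so depth was estimated from the amount at which low values times transcript length pile up in genes with 1 transcript. It came to 13210000 to 23840000 full-read equivalents per library. Only 14.4% to 19.3% of low values were whole multiples of that amount (within 0.02), so counts were not rebuilt and no count-based test was run. Gene symbols, biotypes, transcript lengths, GC content and positions came from the GENCODE mouse annotation and genome of the same build, in which 55154 gene IDs matched and 181 did not. Some symbols of a list matched 2 gene models, each counted as a member. Groups were taken from the labels' condition field, which names the tumour line, genotype and treatment together. None of the 276 pairs of libraries shared more than 0.027% of its nonzero values, so none was a copy of another. In MC38 WT anti-PD-1 replicates 2 and 3 the value column carries the same name and no sample code, and these values were assigned by the record each file belongs to.

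Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1. Within each line, genes with at least 1 FPKM in at least 3 of the 12 libraries were tested, 14209 in MC38 and 13627 in B16. A linear model with 1 mean per group was fitted to the 12 libraries of a line, so that all 4 groups share the estimate of spread. Variances were moderated with a mean-variance trend, p-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. Each line had 6 comparisons: KO against WT under PBS and under anti-PD-1, anti-PD-1 against PBS in WT and in KO, KO against WT averaged over treatments, and the genotype by treatment interaction. A fit of all 24 libraries with 15655 genes tested whether the averaged KO effect differed between lines. The tests, comparisons, gene lists and rule for named genes were chosen before the data were examined, and the comparison of chromosomes and the genes said to fall outside the rule were chosen afterwards.

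A set of 34 gene lists for immune, stromal and contaminating cell types and for tumour pathways was fixed, of which 32 in MC38 and 26 in B16 had at least 5 measured members. Lists were tested with limma's camera at a preset correlation of 0.01, and again with the correlation estimated for each list. Camera compares a list with the other genes. Within each list, gene p-values were also adjusted over the list alone. Limma's fry, which asks whether a list's genes move one way on balance, was run beside it, but its values moved with the order of the model's columns and are not reported here.

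Genes were named by a fixed rule: Chek2, a panel of 8 immune genes (Cd8a, Gzmb, Ifng, Prf1, Pdcd1, Cd274, Cxcl9 and Foxp3), the 8 largest rises and 8 largest falls per simple comparison among called genes without overlap between groups and with at least 1 FPKM in the higher group, 2 members of each called list and, for the interaction and the comparison of lines, the 4 largest in each direction. Unnamed gene models and receptor segments were left out. Foxp3 was under the filter in both lines, and in B16 so were Cd8a, Ifng, Prf1 and Pdcd1. The rule gave 522 gene results, 362 of them called. Wars, and the p53 target and melanocyte genes in the closing section, fell outside it and were chosen after their values were seen.

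The steps were tested on simulated data, normal values drawn with each gene's mean and residual spread in a line, in which 200 genes were raised by known folds in the KO PBS libraries and the members of the CD8 list lowered. These folds are of FPKM + 1, the scale of the analysis. For KO against WT under PBS (14209 genes in MC38, 13627 in B16), limma recovered 73.1% of 67 genes changed 1.5-fold, 92.5% of 67 changed 2-fold and 100% of 66 changed 4-fold in MC38, with 7 false among 189 calls, of which 177 were raised genes and 5 members of the lowered list. For B16 the shares were 43.3%, 82.1% and 98.5%, with 12 false among 162 calls, of which 149 were raised genes and 1 a list member. Camera called a shifted list at 0.7 log2 in MC38 (12 members) and at 1.4 but not 0.7 log2 in B16 (5 members, adjusted p = 0.19 and 2.7e-05). The simulated genes were drawn independently of each other, so this does not test camera on lists whose members are correlated.

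Alternatives were quantile normalization, no filter on low values, a pseudocount of 0.1, limma without the trend, array weights, all 24 libraries in one fit, the compared groups alone, a log2 fold threshold of 1 and leaving out each library in turn. Alternatives added after the data were seen were the removal of each library's trend over transcript length and GC content (loess, span 0.3), protein-coding genes alone rescaled to equal sums, a fit without the B16 KO anti-PD-1 group, leaving out each library or using 1 treatment alone in the comparison of lines, and list members that pass the filter in the 9 B16 libraries outside the KO anti-PD-1 group. Other splits of the libraries were refitted, all 10 for 3 against 3 and 100 drawn at random for the others. Intervals are 95% bootstrap intervals over genes from 2000 draws. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.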

Results

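RNA from tumours of 2 mouse cancer cell lines was sequenced: MC38, a colon carcinoma line, and B16, a melanoma line. In each line the tumours came either from the parental cells, which carry intact Chek2 (WT), or from cells in which Chek2 had been knocked out (KO). Chek2 encodes the checkpoint kinase CHK2, which relays DNA double-strand breaks to cell cycle arrest and p53. The mice received PBS or an antibody against PD-1, an inhibitory receptor of T cells. This made 8 groups of 3 libraries, 12 libraries per line. The deposited values were FPKM (fragment counts scaled to transcript length and library size) for 55335 genes, and the FPKM of one library summed to between 310868 and 398474. The steps between low values put the depth at 13210000 to 23840000 full-read equivalents per library, and replicates of one group correlated across genes at 0.957 to 0.984 (Pearson's r on the log2 scale). Values below are means ± SD of 3 libraries in FPKM, and log2 differences are given ± their standard error. The labels do not say whether the 3 libraries of a group came from separate animals, so every p-value measures the spread between these libraries alone.

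The knocked-out gene was measured first, as a check of the labels. Chek2 (ENSMUSG00000029521, mm10 chromosome 5, 110839979 to 110874145) was lower in the 6 KO libraries than in the 6 WT libraries of the same line. In MC38 tumours under PBS it stood at 5.30 ± 0.775 FPKM in WT and 2.17 ± 0.240 in KO, a log2 difference of -0.99 ± 0.099 (limma adjusted p = 0.000178). Under anti-PD-1 the MC38 means were 5.44 ± 0.376 and 3.22 ± 0.156, a log2 difference of -0.61 ± 0.099 (limma adjusted p = 0.00375). In B16 the means were 7.60 ± 0.389 in WT and 5.66 ± 0.0218 in KO under PBS, and 8.23 ± 0.936 and 6.42 ± 0.381 under anti-PD-1. Averaged over both treatments, Chek2 fell by 0.34 ± 0.061 in B16 on the log2 scale (limma adjusted p = 0.00285) and by 0.80 ± 0.070 in MC38 (limma adjusted p = 3.43e-05). The B16 difference under PBS alone did not pass (limma adjusted p = 0.106, and 0.0369 to 0.305 over 16 alternatives). The B16 difference under anti-PD-1 was called (limma adjusted p = 0.0154), but not without WT anti-PD-1 replicate 2 (0.0597) or without KO anti-PD-1 replicate 2 (0.0516), within 0.00129 to 0.0629 over 15 alternatives. Host cells in the tumour keep intact Chek2, and the values do not separate their transcripts from those of tumour cells. How much of the Chek2 RNA left in KO tumours came from either was not tested, and no protein was measured.

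**Figure D1:**
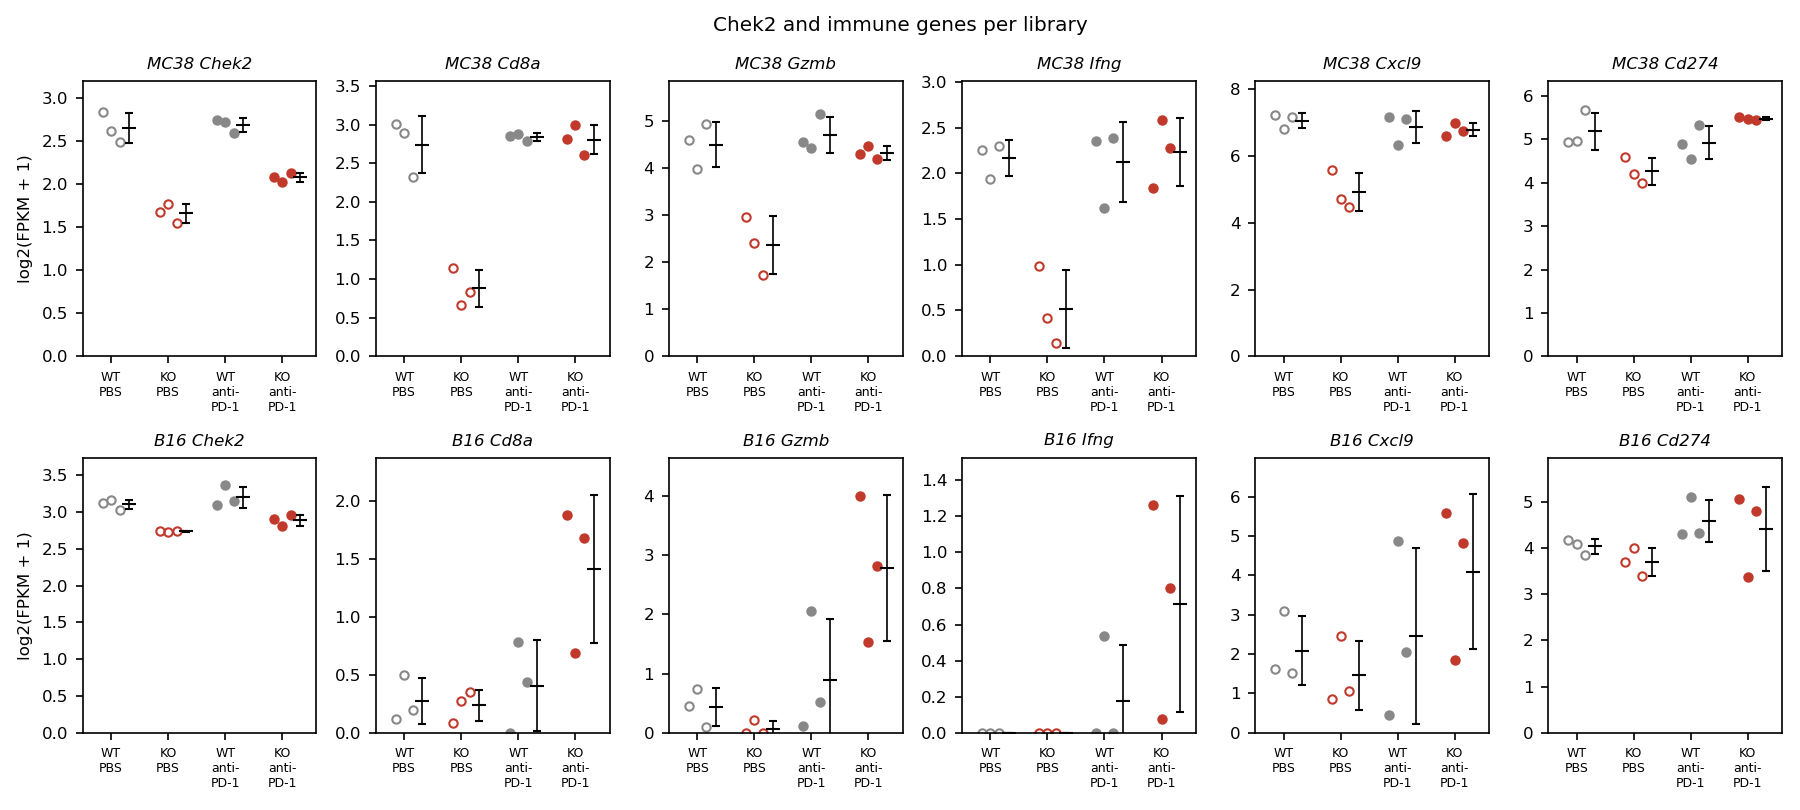
Expression of Chek2 and 5 immune genes as log2(FPKM + 1) in each of the 24 libraries, by tumour line (MC38 above, B16 below), genotype (WT grey, KO red) and treatment (PBS open, anti-PD-1 filled); bars show the mean and SD of 3 libraries on that scale. Among the MC38 groups, KO tumours under PBS lay lowest for Cd8a (0.857 ± 0.321 FPKM), and MC38 KO tumours under anti-PD-1 (6.04 ± 0.914 FPKM) lay near both WT groups.

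The first question was how KO tumours differ from WT tumours without the antibody. In MC38 tumours under PBS, transcripts of T cells, natural killer (NK) cells, macrophages and antigen presentation were lower in KO than in WT. Cd8a, the CD8 co-receptor chain of cytotoxic T cells, stood at 5.83 ± 1.62 FPKM in WT and 0.857 ± 0.321 in KO, a log2 difference of -1.86 ± 0.178 (limma adjusted p = 0.000143). Ifng, the cytokine interferon-gamma, went from 3.52 ± 0.589 to 0.472 ± 0.453 (limma adjusted p = 0.00208), and Gzmb, the cytotoxic granule protease granzyme B, from 22.3 ± 7.35 to 4.44 ± 2.21 (limma adjusted p = 0.00123). All 12 measured members of the list of CD8 T cell and cytotoxic genes fell, over all genes and when adjusted over the list alone, with a median log2 difference of -1.66. Likewise 14 of 14 pan T cell genes fell, 12 of 12 NK cell genes, 9 of 9 MHC class II genes, 12 of 19 MHC class I genes and 9 of 14 macrophage and monocyte genes (14 and 14 for the last pair of lists when adjusted over the list alone). In the interferon-gamma response 19 of 24 genes fell (21 adjusted over the list alone) and 1 rose, Wars, which encodes a tRNA synthetase. Among T cell attracting chemokines and their receptors 9 of 12 fell, among T cell checkpoint genes 6 of 7, and among B and plasma cell genes 4 of 7 (7 adjusted over the list alone). Ccl2, a chemokine that draws monocytes, fell from 226 ± 14.3 to 63.4 ± 10.9 FPKM (limma adjusted p = 6.08e-05). Camera called each of these lists lower, with adjusted p from 1.52e-12 for the CD8 list to 0.00172 for B and plasma cells. None of these calls held when the correlation within each list was estimated: adjusted p = 0.22 with an estimated correlation for the CD8, pan T, NK, MHC class I, chemokine and checkpoint lists, 0.23 for MHC class II, 0.26 for the macrophage and interferon-gamma lists and 0.28 for B and plasma cells.

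Other cell programs moved the opposite way in the same tumours. Of 19 measured hypoxia and glycolysis genes 10 rose (12 adjusted over the list alone) and none fell. Among them, Ero1l, an oxidase of protein folding, rose from 81.9 ± 19.8 to 355.2 ± 10.7 FPKM (limma adjusted p = 0.000291), and Ddit4, a stress-induced brake on mTORC1, from 30.7 ± 1.86 to 91.9 ± 9.34 (limma adjusted p = 7.11e-05). Camera called this list higher (adjusted p = 8.32e-06), with adjusted p = 0.32 with an estimated correlation. In the TGF-beta response 5 of 13 genes rose and 1 fell (camera adjusted p = 0.0322, adjusted p = 0.28 with an estimated correlation). The largest rises by the rule for named genes included Mmp10, a matrix protease, from 0.769 ± 0.379 to 17.0 ± 8.27 FPKM, Ostn, a secreted peptide, from 0.646 ± 0.424 to 12.4 ± 2.23, and Bmp5, a bone morphogenetic protein, from 0.353 ± 0.248 to 8.98 ± 1.12. Igf2, the growth factor IGF-II, fell from 8.38 ± 4.95 to 0.0148 ± 0.00447 FPKM (limma adjusted p = 0.000549), and Grb10, an adaptor that restrains insulin-type receptors, from 16.1 ± 1.88 to 0.844 ± 0.355 (limma adjusted p = 4.36e-05). Small structural RNAs were higher in the KO libraries under PBS than in the other MC38 groups, at 68.0 ± 6.72 against 6.35 ± 2.23 FPKM for the 5.8S ribosomal RNA gene n-R5-8s1 in WT. Such RNAs come from near-identical copies, so the gene assignment is uncertain. The 14 endothelial genes had a median log2 difference of -0.03 and the 20 fibroblast and matrix genes 0.05, and neither list was called.

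Across 14209 tested MC38 genes, limma called 3329 between KO and WT under PBS, 1686 higher and 1643 lower in KO. With protein-coding genes alone the split was 1977 and 1306. Of the 3329 genes, 391 changed at least 2-fold in FPKM + 1 (164 higher and 227 lower). The added 1 shrinks the fold changes of genes with low FPKM, so such counts miss some 2-fold changes in FPKM. At an unadjusted p below 0.05 there were 5316 genes, where 710 are expected by chance, and 39.8% of the tested genes had groups that did not overlap (chance gives 10% for 3 against 3). Camera called 18 of 32 fixed lists, 15 lower and 3 higher. Beyond those described, the lower lists were type I interferon, regulatory T cells, conventional dendritic cells, inflammatory cytokines and cytosolic nucleic acid sensing, with 6 of 23, 3 of 5, 2 of 9, 5 of 12 and 1 of 12 members lower (adjusted p = 0.57, 0.22, 0.22, 0.32 and 0.32 with an estimated correlation). The third higher list held immediate early and stress genes, with 4 of 17 higher (adjusted p = 0.42 with an estimated correlation). Without WT PBS replicate 2 the number of called genes was 2108.

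**Figure D2:**
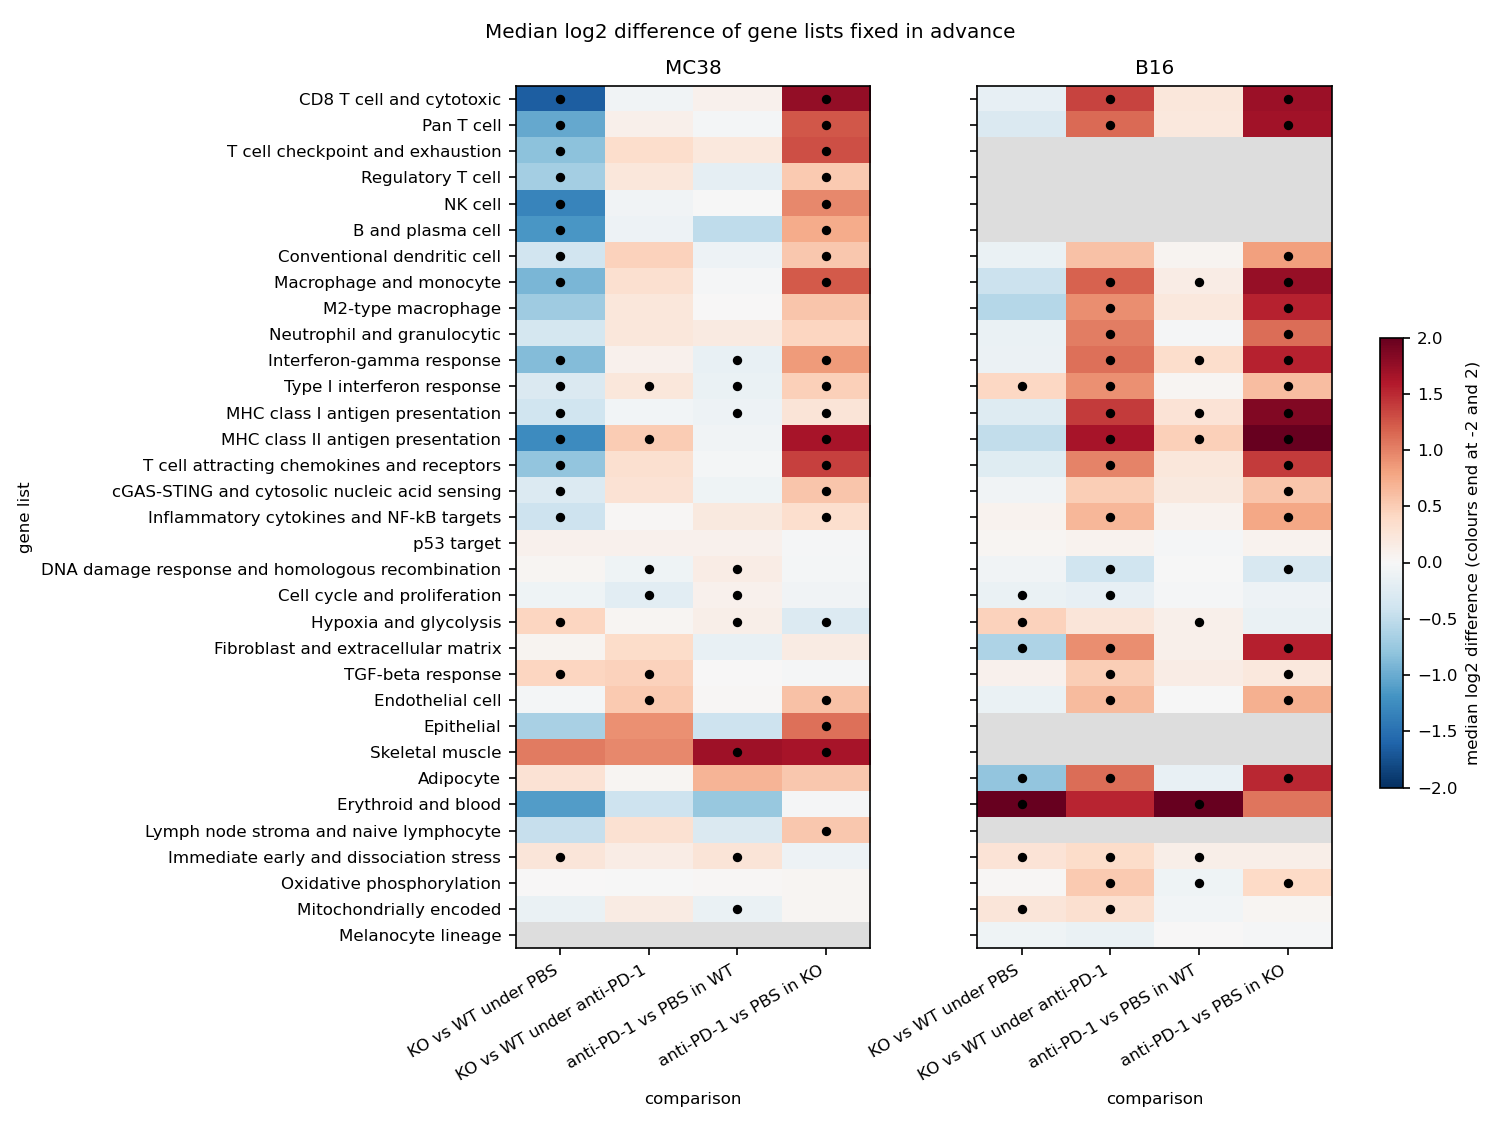
Median log2 difference (colour, ending at -2 and 2) of the members of each gene list fixed in advance, in 4 comparisons per tumour line; a dot marks a list called by camera with its preset correlation, and grey a list with under 5 measured members. MC38 immune lists are lower in KO than WT under PBS and higher under anti-PD-1 than PBS in KO, where the CD8 list has medians of -1.66 and 1.75.

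The next question was whether anti-PD-1 changes these tumours and whether the genotype matters. In MC38 KO tumours the immune transcripts that were low under PBS were higher under anti-PD-1. This difference and the one between KO and WT under PBS share the same 3 KO PBS libraries, so they are not independent. All 12 CD8 T cell and cytotoxic genes rose (median log2 difference 1.75), as did 13 of 14 pan T cell genes, 9 of 9 MHC class II genes, 6 of 7 checkpoint genes, 9 of 12 T cell chemokine genes, 16 of 24 interferon-gamma response genes, 10 of 14 macrophage genes and 8 of 12 NK cell genes. Adjusted over the list alone the numbers for the last 5 lists were 7, 12, 20, 12 and 11. Cd8a rose from 0.857 ± 0.321 to 6.04 ± 0.914 FPKM (limma adjusted p = 0.00044), and Cd274, which encodes the PD-1 ligand PD-L1, from 18.5 ± 4.26 to 43.7 ± 1.23 (limma adjusted p = 0.00914). Trac, the constant part of the T cell receptor alpha chain, rose from 0.980 ± 0.376 to 9.56 ± 4.08 (limma adjusted p = 0.000769), and Tnf, the cytokine TNF, from 1.62 ± 0.511 to 6.31 ± 1.53 (limma adjusted p = 0.00166). Fcgr4, an activating Fc receptor of myeloid cells, rose from 27.3 ± 19.3 to 133.1 ± 12.3 (limma adjusted p = 0.00467). Camera's adjusted p ran from 1.48e-18 for the CD8 list to 1.26e-09 for the checkpoint list. The calls of these 2 lists held when the correlation was estimated (adjusted p = 0.042 with an estimated correlation for each), and the other 6 did not, with adjusted p = 0.071 with an estimated correlation for the pan T, MHC class II, chemokine and NK lists, 0.11 for macrophages and 0.13 for the interferon-gamma response.

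Camera called 20 of 32 lists in that comparison, 19 higher and 1 lower. The lower one was hypoxia and glycolysis, with 1 of 19 genes lower (3 adjusted over the list alone; adjusted p = 0.46 with an estimated correlation). The 5.8S RNA gene n-R5-8s1 fell from 68.0 ± 6.72 to 6.79 ± 3.02 FPKM (limma adjusted p = 0.00044), again from near-identical copies. Limma called 1277 genes, 870 higher and 407 lower under anti-PD-1, with 3373 at an unadjusted p below 0.05 and 30.4% of tested genes without overlap (10% by chance). With protein-coding genes alone, rescaled to equal sums, the split was 826 higher and 687 lower. The count was 730 without KO PBS replicate 2, 684 without KO PBS replicate 3, 616 without KO anti-PD-1 replicate 2 and 790 without KO anti-PD-1 replicate 3.

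In MC38 WT tumours the same antibody left Cd8a at 6.17 ± 0.229 FPKM against 5.83 ± 1.62 under PBS (limma adjusted p = 0.844), and Gzmb at 25.5 ± 7.39 against 22.3 ± 7.35 (limma adjusted p = 0.813). Limma called 0 of 14209 genes, with 1953 at an unadjusted p below 0.05, a smallest adjusted p of 0.0759 (Rab39b and Masp1 among them) and 18.2% of genes without overlap (10% by chance). A fit of all 24 libraries called 79 genes, the fit without a filter on low values 5, and the fit of these 6 libraries alone 3. Camera called 9 lists, among them DNA damage response with a median log2 difference of 0.15, MHC class I at -0.10, type I interferon at -0.14, the interferon-gamma response at -0.15 and hypoxia at 0.12, and skeletal muscle at 1.70. The others were immediate early genes at 0.25, cell cycle at 0.09 and mitochondrially encoded genes at -0.13, the last at 0 after quantile normalization. Each of the 9 had adjusted p = 0.75 with an estimated correlation. Lists called numbered 5 without WT PBS replicate 2, 3 without WT PBS replicate 3 and 2 without WT anti-PD-1 replicate 2. The gene count was 3 without WT PBS replicate 2 or WT anti-PD-1 replicate 2, and 1 without WT PBS replicate 1, WT PBS replicate 3 or WT anti-PD-1 replicate 1.

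The difference between those responses was tested as the genotype by treatment interaction. In MC38 the difference between anti-PD-1 and PBS was larger in KO than in WT for the CD8 list, by a median log2 difference of 1.66, with 9 of 12 members called (12 adjusted over the list alone). Of the pan T cell genes 6 of 14 were called (13 adjusted over the list alone), of MHC class II 6 of 9 (9), of the interferon-gamma response 10 of 24 (19) and of macrophage genes 2 of 14 (13). Cd8a had an interaction of 1.83 ± 0.252 (limma adjusted p = 0.0118) and Trac 2.49 ± 0.342 (limma adjusted p = 0.0118). For these lists camera's adjusted p was 2.41e-16 for CD8 and at most 1.13e-11 for the pan T, MHC class II and interferon-gamma lists. With an estimated correlation none held, with adjusted p = 0.062 with an estimated correlation for CD8, 0.073 for pan T, 0.076 for MHC class II, 0.1 for macrophages and 0.11 for the interferon-gamma response. Limma called 346 genes, 257 with a higher and 89 with a lower response in KO, and 2771 at an unadjusted p below 0.05. This count depended on single libraries: it was 60, 90 and 117 without WT PBS replicates 1 to 3, 110, 85 and 158 without WT anti-PD-1 replicates 1 to 3, 725, 52 and 137 without KO PBS replicates 1 to 3, and 48 and 92 without KO anti-PD-1 replicates 2 and 3. Camera called 22 of 32 lists, 19 higher and 3 lower, the lower ones being hypoxia, DNA damage response and cell cycle (medians of -0.47, -0.18 and -0.12, adjusted p = 0.37, 0.23 and 0.49 with an estimated correlation).

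Under anti-PD-1, MC38 KO and WT tumours did not differ past the threshold in the immune panel and differed in other genes, cell cycle genes among them. Cd8a stood at 6.17 ± 0.229 FPKM in WT and 6.04 ± 0.914 in KO (limma adjusted p = 0.923), and none of the 7 measured panel genes was called by limma. Cd274 was closest, at 30.2 ± 8.45 in WT and 43.7 ± 1.23 in KO, with all 3 KO libraries above the 3 of WT (limma adjusted p = 0.148). Ostn was 3.07 ± 0.183 higher in KO on the log2 scale (limma adjusted p = 3.05e-05), and Ptn, the growth factor pleiotrophin, from 2.23 ± 1.36 to 21.1 ± 9.24 (limma adjusted p = 0.00118). Wnt5a, a noncanonical Wnt ligand, fell from 16.8 ± 0.779 to 3.58 ± 0.230 (limma adjusted p = 4.84e-05), and Tex101, a surface glycoprotein best known from germ cells, from 10.5 ± 3.19 to 0.810 ± 0.140 (limma adjusted p = 0.000121). Of 27 cell cycle genes 4 fell (7 adjusted over the list alone), among them the transcription factor gene E2f1 at 19.4 ± 0.490 in WT and 11.2 ± 1.08 in KO (limma adjusted p = 0.000852), and of 26 DNA damage response genes 5 fell. In the TGF-beta response 4 of 13 rose (7 adjusted over the list alone), among them Tgfb2, the ligand TGF-beta 2, at 0.348 ± 0.0811 and 1.54 ± 0.272 (limma adjusted p = 0.00118), and in the type I interferon response 6 of 23 rose. Camera called these 4 lists plus endothelial cells and MHC class II, each with adjusted p = 0.81 with an estimated correlation. Limma called 1714 genes, 712 higher and 1002 lower in KO, with 3973 at an unadjusted p below 0.05 and 34.1% without overlap (10% by chance). Of the 1714 genes, 162 changed at least 2-fold in FPKM + 1 (91 higher and 71 lower). The count of 1714 fell to 939 and 1066 without WT anti-PD-1 replicates 1 and 3. It fell to 1099, 1137 and 837 without KO anti-PD-1 replicates 1 to 3, and 11 lists were called without KO anti-PD-1 replicate 1.

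Genes called in both treatments pointed largely the same way in MC38. Of the KO against WT calls, 433 were higher and 507 lower under both treatments, where independent lists would share 84.5 and 115.9, and 25 were opposite (201.2 expected). These pairs of groups share no library, and the log2 differences correlated across 14209 genes at 0.393 (Pearson) and 0.345 (Spearman). Averaged over treatments, limma called 3891 genes, 1904 higher and 1987 lower in KO, or 2018 and 1560 with protein-coding genes alone. Of CD8 genes 12 of 12 fell, an average of a fall under PBS and no called member under anti-PD-1, of NK cell genes 11 of 12 and of cell cycle genes 9 of 27, and of hypoxia genes 8 of 19 and of TGF-beta response genes 6 of 13 rose. Camera called 12 lists, 10 lower and 2 higher, and none held when the correlation was estimated (adjusted p = 0.46 with an estimated correlation for the CD8, NK and TGF-beta lists, 0.65 for hypoxia and 0.71 for cell cycle).

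In B16 tumours under PBS, few genes separated KO from WT. Mcmdc2, a meiotic relative of the replicative helicase, rose from 0.198 ± 0.0928 to 5.39 ± 0.338 FPKM (limma adjusted p = 0.00136), and Capn6, a calpain without protease activity, from 6.37 ± 1.17 to 22.5 ± 1.95 (limma adjusted p = 0.00136). Fermt1, the integrin activator kindlin-1, fell from 4.82 ± 2.20 to 0.0129 ± 0.0223 (limma adjusted p = 0.00212). T cell transcripts were near the floor in both genotypes, with Cd8a at most 0.411 FPKM in any of the 6 libraries. Limma called 64 of 13627 genes, 38 higher and 26 lower in KO, with 1810 at an unadjusted p below 0.05 (681 expected) and 21.2% without overlap (10% by chance). The split was 45 and 19 after quantile normalization and 43 and 12 once length and GC trends were removed. More genes were lower than higher with array weights (86 higher and 106 lower) and with all 24 libraries in one fit (145 and 186). Without 1 library the count lay at 11, 17 and 10 (WT PBS replicates 1 to 3) and 10, 14 and 13 (KO PBS replicates 1 to 3). Camera called 8 of 26 lists without a single member past the threshold over all genes. Hypoxia had the smallest p (median 0.46, 8 of 18 higher adjusted over the list alone, camera adjusted p = 9.84e-11), with Hk2, the glycolytic hexokinase, at 48.6 ± 8.49 and 97.8 ± 10.5 FPKM (limma adjusted p = 0.12). Hypoxia, mitochondrially encoded, erythroid, cell cycle and immediate early genes had adjusted p = 0.7 with an estimated correlation, and type I interferon, fibroblast and adipocyte genes 0.98. The mitochondrial median of 0.25 was 0.07 after quantile normalization.

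Under anti-PD-1 the B16 genotypes differed widely. In KO tumours 20 of 21 oxidative phosphorylation genes rose (21 adjusted over the list alone), such as the complex I subunit gene Ndufs3 from 40.5 ± 2.69 to 60.1 ± 2.11 FPKM (limma adjusted p = 0.000232). Of 26 DNA damage response genes 15 fell and 1 rose (17 and 1 adjusted over the list alone), among them Atm, the kinase that activates CHK2, from 9.63 ± 1.94 to 1.46 ± 0.289 FPKM (limma adjusted p = 8.21e-06) and Mdc1, a scaffold of damaged chromatin, from 10.4 ± 1.02 to 5.35 ± 0.772 (limma adjusted p = 0.000158). Of 27 cell cycle genes 12 fell, among them Top2a, topoisomerase II alpha, from 75.8 ± 4.02 to 39.6 ± 3.17 (limma adjusted p = 4.17e-05). Some immune genes were higher: 8 of 19 MHC class I genes, 5 of 14 macrophage genes (1 fell), 4 of 7 pan T cell genes, 3 of 5 CD8 genes and 3 of 23 type I interferon genes. Of all 13627 genes 2034 were higher. In other immune lists few were called higher: 0 of 22 interferon-gamma response genes (median log2 difference 1.096), 0 of 10 T cell chemokine genes (0.986) and 1 of 9 MHC class II genes (1.645). Among members that pass the filter in the other 9 B16 libraries, the pan T cell and CD8 numbers were 1 of 2 and 0 of 1. Nkg7, a cytotoxic granule protein, rose from 0.774 ± 0.846 to 7.08 ± 5.82 (limma adjusted p = 0.0073), and Cd68, a macrophage lysosomal protein, from 24.9 ± 6.29 to 66.8 ± 25.7 (limma adjusted p = 0.00398). Camera's adjusted p was 7.04e-10 for oxidative phosphorylation, 0.000405 for DNA damage response, 0.00061 for MHC class I and 0.0197 for cell cycle. With adjusted p = 0.51 with an estimated correlation for the first 2 of these and 0.52 to 0.54 for the immune and cell cycle lists, none of the 20 called lists (18 higher, 2 lower) held. Several genes were listed at or near 0 FPKM in KO tumours under anti-PD-1: Qser1, a regulator of DNA methylation, stood at 14.8 ± 1.05 in WT and was listed at 0 in all 3 KO libraries, and Zbed6, a transcriptional repressor of Igf2, fell from 22.3 ± 7.82 to 0.821 ± 0.462 (limma adjusted p = 1.15e-05). Without read counts, and in a group that stands apart as a whole, such values do not establish that the transcripts were absent from these tumours.

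The B16 KO anti-PD-1 libraries also stood apart in ways that go beyond these groups. Their FPKM summed to 375193 to 398474, against 319980 to 344059 in the other 9 B16 libraries. Their estimated depth was 19690000 to 23840000 full-read equivalents, against 13570000 to 17450000 in the other 9. Their differences from WT ran with the GC content of the gene, with a Spearman correlation of 0.35 across genes and medians of -0.35 in the lowest and 0.16 in the highest of 5 groups by GC content. They also ran with transcript length (Spearman -0.22), with medians of 0.03 in the shortest and -0.30 in the longest of 5 groups. Skeletal muscle actin Acta1 averaged 263.4 ± 403.2 FPKM there against 0.0876 ± 0.0687 in WT, and haemoglobin transcripts summed to 15524 FPKM in replicate 1. Limma called 5560 genes, 2034 higher and 3526 lower in KO, with 6838 at an unadjusted p below 0.05 and 50.8% without overlap (10% by chance). Once length and GC trends were removed, the split was 2142 and 2298, and with protein-coding genes alone 659 and 4217, a rescaling that moved the median of all genes by -0.17. With the trends removed, 14 of 21 oxidative phosphorylation genes were still higher (median log2 difference 0.50, against 0.52 before) and 13 of 26 DNA damage genes lower (-0.31, against -0.41). Without KO anti-PD-1 replicate 1, 6 lists were called, and no MHC class I member was called, while 16 of 21 oxidative phosphorylation genes were higher and 13 of 26 DNA damage genes lower.

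**Figure D3:**
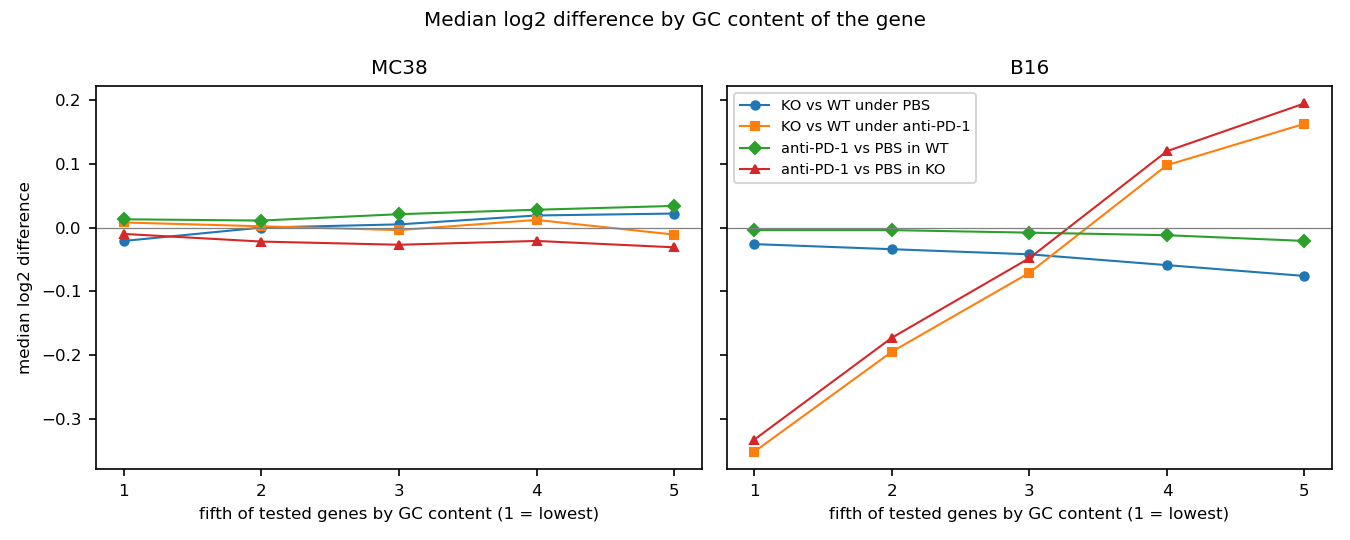
Median log2 difference of the tested genes in 5 groups of equal size by GC content (x axis, 1 lowest) for 4 comparisons in MC38 (left) and B16 (right). Both comparisons that involve B16 KO tumours under anti-PD-1 climb with GC content, KO against WT from -0.35 to 0.16, and the other lines stay within 0.08 of 0.

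In B16 KO tumours immune, stromal and respiratory genes were higher under anti-PD-1 than under PBS. The 7 measured pan T cell genes and 5 measured CD8 genes rose, as did 14 of 19 MHC class I genes, 8 of 9 MHC class II genes, 12 of 14 macrophage genes, 11 of 19 fibroblast genes, 7 of 22 interferon-gamma response genes and 16 of 21 oxidative phosphorylation genes. Most of these T cell genes pass the filter only through the KO anti-PD-1 libraries, which selects for a rise: 2 of the 7 and 1 of the 5 pass it in the other 9 B16 libraries. Without the filter, 12 of 17 pan T cell genes and 9 of 14 CD8 genes rose, with median log2 differences of 0.90 and 1.12 against 1.68 and 1.72 with it. Of the members that pass in the other 9 libraries, 11 of 13 macrophage, 14 of 19 MHC class I and 7 of 7 MHC class II genes rose. For the interferon-gamma response it was 4 of 18, where 2580 of all 13627 genes were higher. Adjusted over the list alone, 19 oxidative phosphorylation and 17 fibroblast genes rose. Genes of neighbouring tissue rose too, 3 of 3 measured for skeletal muscle (median log2 difference 4.82) and 6 of 8 for adipocytes (1.505). Among those that pass the filter in the other 9 B16 libraries, 1 of 1 and 4 of 5 rose. In the type I interferon response 2 of 23 genes rose. Gzmb rose from 0.0523 ± 0.0906 to 7.63 ± 6.69 FPKM (limma adjusted p = 0.00387), Trac from 0.0830 ± 0.144 to 3.74 ± 2.15 (limma adjusted p = 0.000618) and the class II gene H2-Ab1 by 3.43 ± 0.813 on the log2 scale from 3.04 ± 1.49 FPKM (limma adjusted p = 0.00655). Of 26 DNA damage response genes 12 fell and 1 rose, with Atm at 8.82 ± 0.647 under PBS and 1.46 ± 0.289 under anti-PD-1. Camera called 19 of 26 lists, 18 higher and 1 lower, and none with the correlation estimated (adjusted p = 0.47 with an estimated correlation for most, 0.52 for the interferon-gamma response). Limma called 5988 genes, 2580 higher and 3408 lower, with 7135 at an unadjusted p below 0.05. Once length and GC trends were removed the split was even, at 2467 and 2420. With protein-coding genes alone it was 1009 and 4145, with the median of all genes moved by -0.18, and without KO anti-PD-1 replicate 1 camera called 12 lists.

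In B16 WT tumours limma called 0 of 13627 genes between anti-PD-1 and PBS, with 281 at an unadjusted p below 0.05, where 681 are expected by chance, a smallest adjusted p of 1 and 6.5% of genes without overlap (10% by chance). The fit of these 6 libraries alone called 3 genes, the fit without the KO anti-PD-1 group 2 and that of all 24 libraries 1, as did the fit without WT PBS replicate 2. Cd274 stood at 23.7 ± 8.28 FPKM against 15.4 ± 1.78 under PBS (limma adjusted p = 1). Camera called 8 lists, among them erythroid at 2.13, MHC class II at 0.48 and the interferon-gamma response at 0.35, each with adjusted p = 0.86 with an estimated correlation, and the number was 14 and 4 without WT anti-PD-1 replicates 1 and 2 and 3 and 1 without WT PBS replicates 1 and 3.

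As an interaction, 3203 B16 genes responded differently to anti-PD-1 in KO and WT, 1213 more and 1990 less in KO, or 871 and 1201 once length and GC trends were removed and 321 and 2475 with protein-coding genes alone, which moved the median of all genes by -0.17. The response was higher in KO for 10 of 21 oxidative phosphorylation genes (18 adjusted over the list alone) and for 4 of 7 pan T cell genes (1 of 2 that pass the filter in the other 9 libraries), and lower for 9 of 26 DNA damage response genes (11 adjusted over the list alone). Trac had an interaction of 1.95 ± 0.444 (limma adjusted p = 0.0115) and Atm -2.08 ± 0.191 (limma adjusted p = 0.000308). Camera called 14 lists, 13 higher and 1 lower, with adjusted p = 0.62 with an estimated correlation for these 3, and 6 lists without KO anti-PD-1 replicate 1. In other immune lists limma called 0 of 19 MHC class I, 0 of 9 MHC class II, 0 of 22 interferon-gamma response and 0 of 23 type I interferon genes. Their median interactions were 1.597, 2.144, 1.091 and 0.504 on the log2 scale. Averaged over treatments, B16 KO differed from WT in 3616 genes, 1028 higher and 2588 lower, or 1271 and 1478 once length and GC trends were removed and 414 and 3375 with protein-coding genes alone. The B16 KO effects under PBS and under anti-PD-1 correlated across genes at -0.022 (Pearson) and -0.005 (Spearman). Among the called genes, 25 were higher in both (5.7 expected of independent lists), 8 lower in both (6.7 expected) and 3 opposite (13.7 expected). Camera called 18 lists there, 9 without WT anti-PD-1 replicate 1 and 8 without KO anti-PD-1 replicate 1. Oxidative phosphorylation rose in 14 of 21 genes and DNA damage response fell in 15 of 26 (adjusted p = 0.55 with an estimated correlation for each).

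The difference between KO and WT tumours, called the KO effect here, was then compared between the lines. In each line a difference between cell clones is confounded with genotype, so the KO effect cannot be told apart from it. In a fit of all 24 libraries, 4898 of 15655 genes had a KO effect that differed between MC38 and B16, 1811 higher and 3087 lower in B16, or 2307 and 2222 once length and GC trends were removed and 921 and 3751 with protein-coding genes alone. With the KO effect under PBS alone the count was 1481 (538 higher and 943 lower), and under anti-PD-1 alone 4975 (1941 and 3034), so much of it rests on the B16 KO anti-PD-1 group that stands apart. Ostn, Bmp5 and Mmp10, which rose in MC38 KO tumours by 3.06, 2.70 and 3.01 on the log2 scale, had B16 log2 differences of 0.16, 0.01 and 0.08 (limma adjusted p of the difference 1.11e-08, 1.37e-09 and 1.15e-06). Fermt1 fell by 2.45 under PBS and by 2.54 under anti-PD-1 in B16 on the log2 scale, with a log2 difference of -0.02 in MC38 (limma adjusted p of the difference 2.54e-08). Averaged over treatments, KO effects of the lines correlated at -0.07 (Pearson) and -0.09 (Spearman) across 12378 genes measured in both. Under PBS alone the values were 0.112 and 0.126, and under anti-PD-1 alone 0.095 and 0.072. The response to anti-PD-1 in KO tumours had a Pearson correlation of 0.416 and a Spearman correlation of 0.296 between the lines, with 319 genes higher in both (129.6 expected of independent lists), 134 lower in both (85.3 expected) and 77 opposite (229.5 expected). Genes are not independent replicates, so no p-value is attached to these correlations.

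Along the chromosomes, chromosome 13 lay lowest in B16 KO tumours relative to WT, a comparison chosen after its values were seen. The 404 tested protein-coding genes of chromosome 13 had a median log2 difference of -0.24 between KO and WT under PBS, and 81.7% of them lay below the median of the other chromosomes (70% under anti-PD-1). The next lowest was chromosome 8, at -0.12. Other chromosomes were shifted too. Relative to the others, chromosome 6 lay at 0.114 under PBS, with 22.7% of its genes below their median, and at 0.025 under anti-PD-1. Chromosome 18 lay at 0.001 under PBS and -0.17 under anti-PD-1.

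**Figure D4:**
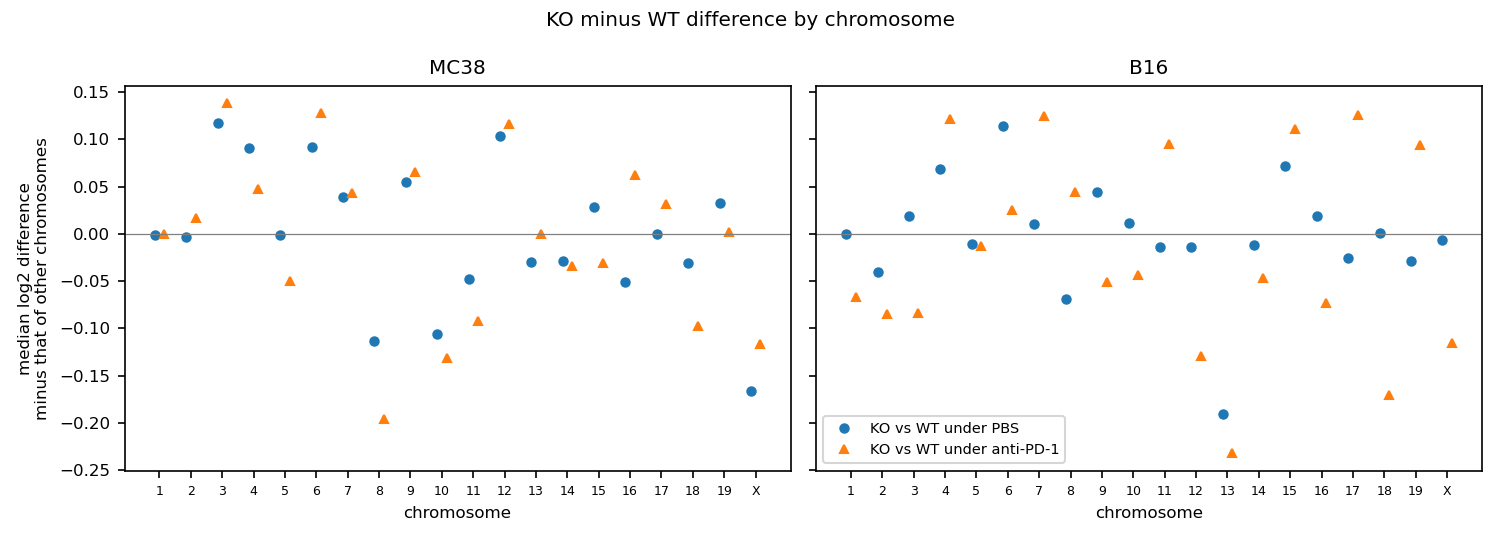
Median log2 difference between KO and WT of the protein-coding genes on each chromosome minus that of all other chromosomes, under PBS (circles) and anti-PD-1 (triangles), in MC38 (left) and B16 (right). B16 chromosome 13 is lowest under both treatments, at -0.19 and -0.23.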

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

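The tests below were written before their results were seen, except that by 10 Mb bins on chromosome 13, and the removal of length and GC trends, the rescaled protein-coding genes the left-out libraries and single treatments in the comparison of lines, and the list members that pass the filter outside the B16 KO anti-PD-1 group were added after the data had been seen.

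MC38 immune genes differed between anti-PD-1 and PBS more in KO than in WT tumours, and the test of that difference singled out 346 genes. For Cd8a it rests on the 3 KO PBS libraries, which averaged 0.857 FPKM against 5.83 to 6.17 in the other 3 MC38 groups, so it does not separate a response to treatment from a low starting level in those libraries. Cd8a had a difference in response of 1.83 on the log2 scale (limma adjusted p = 0.0118) and Trac of 2.49 (limma adjusted p = 0.0118), and both were called in 12 of 12 fits that left out 1 library. Ifng (1.76, limma adjusted p = 0.0414), Igf2 (2.65, limma adjusted p = 0.0386) and H2-Eb1 (2.35, limma adjusted p = 0.0332) were called without KO PBS replicate 1 and without KO anti-PD-1 replicate 1, and lost their call without any one of the other 10 libraries, with limma adjusted p up to 0.106, 0.0875 and 0.0827. Cd274 (1.48, limma adjusted p = 0.0463) was called in 2 of the 12 fits, and Cxcl9 (2.06, limma adjusted p = 0.0332) and H2-Aa (2.47, limma adjusted p = 0.0308) in 3, with the highest values of 0.106, 0.0853 and 0.077 without KO anti-PD-1 replicate 2. Over 20 alternatives each, limma adjusted p ran from 0.0127 to 0.122 for Ifng, 0.0053 to 0.11 for Igf2, 0.00134 to 0.234 for H2-Eb1, 0.02 to 0.126 for Cd274, 0.00481 to 0.452 for Cxcl9 and 0.00101 to 0.238 for H2-Aa.

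Small structural RNAs differed the other way in MC38, and as near-identical copies they are uncertain. Rn7s6 (-3.41, listed at 0 in WT under PBS and in KO under anti-PD-1) and n-R5-8s1 (-3.27) were called in 12 of 12 fits without 1 library. Rn7s1 (-3.19) and Rny1 (-1.92) were called in 2 of the 12, with limma adjusted p up to 0.108 without KO anti-PD-1 replicate 2 and up to 0.0991 without WT PBS replicate 2. Over 19 alternatives the ranges were 0.00385 to 0.126 and 0.0176 to 0.15.

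In B16 the KO response to anti-PD-1 differed from that of WT in 3203 genes. Acta1 (5.70), the fat cell protease gene Cfd (4.64), Hp (3.99), which encodes haptoglobin, and Arg1 (3.96), an arginase of myeloid cells, responded more in KO. Acta1 was called in 0 of the 9 fits without 1 library that could test it (limma adjusted p = 0.0698 to 0.0833) and Cfd in 3 of 12 (up to 0.0851 without WT anti-PD-1 replicate 3), while Hp and Arg1 were called in 12 of 12. Over their alternatives limma adjusted p ran from 0.0152 to 0.127 for Acta1, 0.0104 to 0.109 for Cfd, 0.00407 to 0.0705 for Hp and 0.0025 to 0.0606 for Arg1. Mir8112 (-4.12), the integrin gene Itgav (-3.88), Qser1 (-3.80) and Zbed6 (-3.50) had a lower difference between anti-PD-1 and PBS in KO and were called in 12 of 12. Leaving out 1 library cannot test a fault shared by all libraries of the KO anti-PD-1 group, which stands apart as a whole. Qser1 and Zbed6 were listed at or near 0 FPKM there, which does not establish that their transcripts were absent.

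Between the lines, the KO effect differed in 4898 genes, in 1481 under PBS alone and in 4975 under anti-PD-1 alone, where the B16 KO group stands apart. In B16 relative to MC38 it was higher for mt-Ts2, a mitochondrial tRNA, by 5.74, and lower for Mmp10 (-2.93), Ostn (-2.90), Bmp5 (-2.69) and Fermt1 (-2.48), each called in 24 of 24 fits without 1 library. The latter 4 were also called under each treatment alone, and mt-Ts2 not under PBS alone (limma adjusted p = 0.313, the highest of a range from 0.000892 over 31 alternatives). For mt-Ts2 the log2 difference between KO and WT was -3.71 in MC38 (limma adjusted p = 0.0193). In B16 it was 2.03 and not called (limma adjusted p = 0.178). The fall of Chek2 itself was smaller in B16 by 0.46 (limma adjusted p = 0.000749, and 0.000134 to 0.0793 over 32 alternatives), and was not called under anti-PD-1 alone. Haemoglobin genes were higher, with Hba-a1 at 3.10, Hbb-bt at 3.07 and Hba-a2 at 3.05. They were called in 17, 11 and 16 of 24 fits, with limma adjusted p up to 0.0572, 0.0722 and 0.0629 without B16 WT anti-PD-1 replicate 3, and up to 0.221, 0.317 and 0.253 over 32 alternatives, the highest being those under anti-PD-1 alone, and none of the 3 was called under PBS alone. All 3 also lost the call without MC38 WT anti-PD-1 replicate 3 (0.0503, 0.0651 and 0.0552), MC38 KO PBS replicate 2 (0.0517, 0.0633 and 0.056), MC38 KO anti-PD-1 replicate 1 (0.0554, 0.0704 and 0.0607), B16 KO PBS replicate 1 (0.0561, 0.069 and 0.0611), B16 KO PBS replicate 2 (0.0558, 0.0701 and 0.0609) and B16 KO anti-PD-1 replicate 1 (0.0525, 0.068 and 0.0587). Without MC38 KO PBS replicate 3, Hbb-bt (0.0597) and Hba-a2 (0.0534) lost it, and Hbb-bt also without MC38 WT PBS replicates 1 to 3 (0.0512, 0.0508 and 0.052) and B16 WT PBS replicates 2 and 3 (0.0515 and 0.0562).

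The first pattern weighed was the low level of immune lists in MC38 KO tumours under PBS. A lower share of host cells of every kind would lower endothelial and fibroblast genes too, but their 34 members had a median log2 difference of -0.023 (95% interval -0.102 to 0.068) against -1.66 for the CD8 list. Apart, the endothelial list had -0.033 (95% interval -0.102 to 0.011) and the fibroblast list 0.049 (95% interval -0.483 to 0.246). The values do not separate host from tumour transcripts, so the fibroblast and matrix genes are the weaker measure of host cells. Intervals here and below run over genes and hold no spread between libraries. Reads taken up by small RNAs and trends with length or GC content are also argued against, since the CD8 median was -1.65 (95% interval -1.97 to -1.25) in rescaled protein-coding genes and -1.65 (95% interval -2.06 to -1.32) with the trends removed. An effect of Chek2 loss on immune infiltration before treatment stays open and was not tested apart from genotype. A difference between cell clones, in tumour size or sampling, or in the preparation or RNA quality of these 3 libraries, in which n-R5-8s1 stood at 68.0 FPKM against 6.35 in WT, stays open too, since the design confounds each with the group.

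The second pattern was the distance of B16 KO tumours under anti-PD-1 from the other B16 groups. A trend with GC content or length is argued against as the whole cause, since 4440 genes were called with the trends removed against 5560 before, the oxidative phosphorylation median was 0.50 against 0.52, and the 72 members of 6 immune lists had a median log2 difference of 1.25 (95% interval from 1.14 up) against 1.28, or 1.33 against 1.34 in the 57 that pass the filter in the other 9 B16 libraries. The library richest in muscle and haemoglobin transcripts does not account for the number of genes either, since 4169 were called without KO anti-PD-1 replicate 1. It does carry part of the immune rise, whose median in the 55 members measured without it was 0.86 (95% interval 0.64 to 0.95), against 1.35 (95% interval 1.17 to 1.48) in the same 55 with all libraries. A library batch or a difference in RNA quality in these 3 libraries may still be the source of part of it and cannot be excluded, because all 3 belong to 1 group and the labels give no batch.

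The third pattern was the lower expression of chromosome 13 in B16 KO tumours, picked as the lowest of the chromosomes, so no p-value is given. A trend with GC content or length is argued against under PBS, where chromosome 13 lay at -0.20 (95% interval -0.22 to -0.17) relative to the others with the trends removed, and under anti-PD-1 removal moved it from -0.23 to -0.10 (95% interval -0.15 to -0.05). Fewer copies of the chromosome in the KO cells were expected to put every bin of 10 Mb below the other chromosomes under both treatments. Below them lay 11 of 11 bins under PBS and 10 of 11 under anti-PD-1, which does not decide it. No DNA was measured, so this stays open.

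Other splits of the libraries were refitted for each count. For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real and the highest other count were 3329 and 3 for MC38 KO against WT under PBS, 1714 and 3 under anti-PD-1, 1277 and 1 for anti-PD-1 against PBS in MC38 KO and 0 and 3 in MC38 WT. In B16 they were 64 and 2 for KO against WT under PBS, 5560 and 87 under anti-PD-1, 5988 and 1 for anti-PD-1 against PBS in KO, and 0 and 1 in WT. For the averaged effects genotype was redrawn within each treatment. In MC38 (3891, highest other 1574) and in B16 (3616, highest other 3291), 1 of 100 splits, the real one, gave as many genes. A redrawn split can keep the real groups of 1 treatment and so that treatment's difference. The splits therefore do not exclude chance for an effect shared by both treatments. For the interactions all 4 groups were redrawn, and for the comparison of lines genotype was redrawn within each line and treatment. These splits mix the other group effects into the result and do not test the difference alone, so they do not exclude chance for it: 3 of 100 gave as many genes for the MC38 interaction (346, highest other 2636), 1 of 100 for the B16 interaction (3203, highest other 2331) and 1 of 100 for the comparison of lines (4898, highest other 3315). A split with several times the real MC38 count points to a structure of the samples, which the real genotype and treatment groups can supply. No further structure was tested.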

How the results depend on the processing

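The alternatives that removed length and GC trends, used protein-coding genes alone, left out the B16 KO anti-PD-1 group or left out libraries or used 1 treatment in the comparison of lines were added after the data had been seen. Of 362 called gene results within a line, 267 were called in each fit without 1 library, and no named gene reversed. Each such fit leaves 2 libraries in 1 group. No paired analysis was possible because the labels carry no replicate numbers or animal identities that link libraries across groups. The alternatives planned for count data were not run, as the files hold FPKM, and the fit of the compared groups alone applies to the 4 simple comparisons. The cause was not tested for the values below, except that a fold threshold and a fit without 1 library use fewer genes or samples by construction. With the spread of the B16 libraries, 43.3% of simulated 1.5-fold changes were recovered in B16 under PBS, so small changes there are under-counted.

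With the correlation estimated per list, camera called 2 lists for anti-PD-1 against PBS in MC38 KO tumours and 0 in the other 11 comparisons. With at least 2-fold change required, the MC38 counts were 391 (KO against WT under PBS), 162 (under anti-PD-1), 370 (anti-PD-1 against PBS in KO), 188 (averaged) and 174 (interaction), and the B16 counts 24, 698, 954, 58 and 661 in that order.

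Without a filter on low values, limma called 5 genes and camera 15 lists for anti-PD-1 in MC38 WT, and camera 2 lists in B16 WT. The MC38 interaction then had 45 genes and B16 KO against WT under PBS 33. With all 24 libraries in one fit these counts were 79 for MC38 WT, 1 for B16 WT, 218 for the MC38 interaction and 331 for B16 under PBS. The compared groups alone gave 3 genes for anti-PD-1 in MC38 WT, 644 in MC38 KO, 3 in B16 WT and 24 for B16 KO against WT under PBS. Array weights gave 651 for the MC38 interaction and 192 for B16 under PBS. For B16 under PBS, limma without the trend gave 41, a pseudocount of 0.1 gave 42 and protein-coding genes alone 17. The B16 interaction had 2072 genes with length and GC trends removed, and anti-PD-1 in B16 WT had 2 without the KO anti-PD-1 group.

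Without 1 library, the MC38 counts of genes ran from 2108 to 2850 for KO against WT under PBS, 837 to 1283 under anti-PD-1, 0 to 3 for anti-PD-1 in WT, 616 to 1358 in KO, 3123 to 3671 averaged and 48 to 725 for the interaction. The lists called ran from 14 to 20, 5 to 11, 2 to 13, 17 to 23, 9 to 15 and 20 to 24 in that order. In B16 the genes ran from 10 to 17, 4119 to 5326, 0 to 1, 4493 to 5585, 2666 to 3567 and 2162 to 3305, and the lists from 6 to 9, 6 to 22, 1 to 14, 12 to 18, 8 to 20 and 6 to 18. The comparison of lines ran from 4418 to 5006, and had 1481 genes under PBS alone.

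Among named gene results, 518 of the values without 1 library lost their call, 68 gained one and 3687 kept their side. The fit without a filter lost 95 calls, the fit of all 24 libraries lost 61 and gained 38, and quantile normalization lost 17 and gained 16.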

Other observations

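The gene lists and their tests were fixed beforehand. Which of them appear in this part, the genes outside the naming rule and the comparison of chromosomes were chosen after the results were seen.

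Some genes activated by p53 rose in MC38 KO tumours, although CHK2 is a kinase upstream of p53. Of 21 measured p53 target genes, 7 rose and 2 fell between KO and WT under PBS (7 and 3 adjusted over the list alone), with a median log2 difference of 0.08, against 1686 higher and 1643 lower of all 14209 genes. Camera did not call the list (adjusted p = 0.165, adjusted p = 0.29 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose by 1.32 ± 0.130 on the log2 scale to 26.5 ± 2.56 FPKM (limma adjusted p = 0.000161), and Phlda3, a brake on AKT signalling, from 27.4 ± 2.25 to 54.0 ± 2.17 (limma adjusted p = 0.000143). Sesn1, a stress-response gene, went from 8.14 ± 1.60 to 4.14 ± 0.897 (limma adjusted p = 0.00669). Under anti-PD-1, 4 of the 21 rose and 1 fell (5 and 1 adjusted over the list alone). In B16 under anti-PD-1, 4 of 18 rose and 4 fell (4 and 4 adjusted over the list alone), with Cdkn1a at 43.1 ± 8.42 and 72.8 ± 8.59 FPKM (limma adjusted p = 0.0013).

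Some pigment cell genes were lower in B16 KO tumours under anti-PD-1, but as a list they did not stand out from all genes. Of 16 melanocyte genes 5 fell and 1 rose (5 and 1 adjusted over the list alone), against 3526 lower and 2034 higher of all 13627 genes, and camera did not call the list (adjusted p = 0.249). Tyrp1, a melanin enzyme, went from 1434 ± 142 to 792 ± 115 FPKM (limma adjusted p = 0.000646) and Mitf, the melanocyte master regulator, from 150.7 ± 17.6 to 91.4 ± 17.2 (limma adjusted p = 0.00429), while Mlana, a melanosome protein, rose by 0.43 ± 0.098 on the log2 scale (limma adjusted p = 0.00557).

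Signal from neighbouring tissue varied between libraries. Skeletal muscle genes had median log2 differences of 1.70 and 1.65 under anti-PD-1 against PBS in MC38 WT and KO tumours, with 0 of 12 genes called by limma in either. In B16 KO tumours under PBS, erythroid genes had a median log2 difference of 2.68 from WT, with 0 of 5 called by limma. Chromosomes also differed in MC38 KO tumours, in the same direction under both treatments: relative to the others, chromosome 8 lay at -0.11 under PBS and -0.20 under anti-PD-1, chromosome X at -0.17 and -0.12, and chromosome 3 at 0.12 and 0.14.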
